A study of Mus musculus with 21 samples.

How the data were processed

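RNA from mouse liver and liver tumours was labelled with Cy3 and hybridised to 21 one-colour Agilent arrays, 1 array per sample, 44397 spots each. The arrays held 7 tumours induced by N-nitrosodiethylamine (DEN) in mice with intact Trp53, 6 tumours and 4 livers of Trp53 knockout (KO) mice, and 4 livers of untreated wild-type (WT) mice. Per the file headers, the authors read the arrays with Agilent Feature Extraction 10.7.3.1, and the deposited files give a processed intensity per spot, corrected for background and for spatial trends, in arbitrary units. The same deposited files mark each spot as well above background or not, as saturated, and as a non-uniform or population outlier. The authors' table of values for the series is in log2 units. Checked against the arrays, each of its columns lay close to the log2 processed intensity of its own array after a shift by the array's 75th percentile and after centring each probe on its median over the 21 arrays. The largest median absolute difference from the own array was 0.0117, the lowest correlation with it 0.9997, and the best with another array 0.858.

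Spots marked as outliers were removed (70 to 397 per array), and the remaining spots of a probe were averaged as log2 processed intensity. The 75th percentile of the 39429 non-control probes was then subtracted on each array. This left 969 values missing, in 768 probes. In all arrays together 5 spots were saturated. Probes well above background on at least 4 of the 21 arrays were kept (30397 probes). Names came from a RefSeq gene table of another build (GRCm38.p6), used for names only. Of the probes, 26761 matched it by their main accession, 93 by another accession and 3752 by symbol, and 8823 kept the name in the files. The probe with the highest mean signal stood for a gene, which gave 23702 genes to test, 19658 of them with a symbol from the table. Coordinates are those of the probes in the array files, in build mm9. A probe does not cover a whole transcript, and related genes such as those of the Sult2a, Reg3, Mup and Cyp2b families may share signal.

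The number before the T in a tumour's title was read as the mouse, and the numbers of the livers as separate mice. This reading gave 5 DEN tumour mice (mice 4 and 5 with 2 tumours each) and 5 KO tumour mice (mouse 5 with 2 tumours). Tumours of 1 mouse were averaged, so that the fit held 18 mice. Sexes, ages, the exons deleted in Trp53 and the cells they were deleted in are not given in the sources used here.

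One limma model with 4 group means was fitted across all genes (R 4.3.3, limma 3.58.1, data.table version 1.17.8), with moderated two-sided tests (prior degrees of freedom 2.62), Benjamini-Hochberg adjustment within each comparison and an adjusted p threshold of 0.05. The comparisons were KO tumour against KO liver, DEN tumour against WT liver, KO tumour against DEN tumour, KO liver against WT liver, and the difference between the first pair of tumour effects. No paired analysis was possible because the labels do not pair tumours with livers. Lists of genes fixed beforehand (25 lists, 391 of 393 members matched to the arrays) were tested with limma's camera at a preset correlation between genes of 0.01, and again with an estimated correlation, where at least 5 members were measured (24 lists). The lists cover p53 targets; biliary, mature hepatocyte, oncofetal and cell cycle genes; Wnt and perivenous, periportal, ERK, Notch, YAP and NRF2 genes; glycolysis and hypoxia, cholesterol and fatty acid synthesis, and interferon response; matrix and stellate, endothelial, macrophage, T and NK, B and plasma, neutrophil, erythroid and pancreatic acinar cells; male- and female-biased liver genes; and, for identity only, Y-linked genes and Xist. A list's score in a mouse is the mean of its genes after subtracting each gene's mean over the 8 livers. Scores of tumours were compared with exact two-sided permutation tests. Overlaps of calls were tested with Fisher's exact test.

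Named genes followed a rule written beforehand. For each comparison they were the 8 highest and 8 lowest log2 fold changes among genes past the threshold. The mice of the groups could not overlap, and the gene had to be well above background on every array of the higher group. For the difference of the tumour effects the overlap condition was not applied. There the background condition asked for all arrays of KO tumours or of WT livers for a rise, and of DEN tumours or of KO livers for a fall. Y-linked genes, Xist and unnamed transcripts were left out of that part. From each list up to 2 risen and 2 fallen members with the smallest adjusted p were added, and 14 genes were always named: Trp53, Cdkn1a, Mdm2, Alb, Afp, Krt19, Krt7, Sox9, Epcam, Spp1, Mki67, Glul, H19 and Igf2. This made 405 named results. Other probes of the gene existed for 93 of them, and in 14 at least 1 other probe moved the opposite way. Where no probe of a gene was well above background on any array of the lower group, its fold change is a lower bound. It was computed against each array's lowest signal that was well above background.

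On simulated data with 200 changed genes of 23453, calls in KO tumour against KO liver recovered 28.4% of changes of 1 log2 unit, 67.2% of 2 and 93.9% of 4, and 5.84% of calls were false. In DEN tumour against WT liver the shares were 28.4%, 74.6% and 92.4%, with 6.25% false. In KO tumour against DEN tumour they were 19.4%, 79.1% and 98.5%, with 2.88% false. In KO liver against WT liver they were 29.9%, 71.6% and 97.0%, with 6.90% false. For the difference of the tumour effects they were 11.9%, 38.8% and 86.4%, with 5.21% false. In each, the list shifted in the simulation was called and no other. The simulated noise was independent between genes, whereas the estimated correlation within lists was 0.029 to 0.810 in the data. Far fewer genes were changed than were called in most comparisons of the data. The simulation therefore says nothing about false list calls among correlated genes.

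The alternatives were other scalings (normexp background correction with an offset of 50 and quantile normalisation, quantile normalisation of the processed signal, scaling on the median of the 17762 probes well above background on all arrays, and the authors' values), no filter or a filter on every array of a group, the mean of a gene's probes, each tumour as its own replicate, mouse or slide as a random block, scan day as a fixed block, array weights, an intensity trend with a robust prior, a fit of only the 2 groups compared, and leaving out each mouse. Chosen after seeing the data were a fit within scan day 1, fits without KO tumour mice 1 and 2, without KO tumour mice 4 and 5, without 5 arrays whose quality report asked for evaluation, and without the sex-biased and sex-linked lists. Each slide held a single group, and the WT livers alone filled their slide and scan day. Comparisons with WT liver therefore cannot be freed of slide and day. Slide as a random block only sets the group difference against a spread between slides. That spread comes from the tumour groups, since each liver group had a single slide. Raw mean signal and local background were used for the normexp alternative alone. Results of some single genes are not reported here. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.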

Results

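The data were transcript levels in mouse liver and liver tumours of C57BL/6J background, read on 21 one-colour microarrays. The 7 DEN tumours, labelled hepatocellular carcinoma, came from 5 mice with intact Trp53 that had received the liver carcinogen N-nitrosodiethylamine (DEN, 10 µg per g body weight, at day 15). The 6 knockout (KO) tumours came from 5 untreated Trp53 knockout mice and carried the combined label hepatocellular and cholangiocellular carcinoma, which does not say whether each tumour held both types. In which cells Trp53 was deleted is not given in the sources used here. KO livers and wild-type (WT) livers without tumour came from 4 untreated mice each. The 75th percentile of the processed intensity was 512 to 884 on DEN tumour arrays, 951 to 4258 on KO tumour arrays, 499.6 to 685 on KO liver arrays and 476 to 729 on WT liver arrays. The share of probes well above background was 65.0 to 82.3%, 54.4 to 76.5%, 51.0 to 56.5% and 57.8 to 63.3% in the same order. The number of arrays limits the precision of every value.

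Changes are given as log2 fold changes with their standard error, from the mean of each mouse's tumours, and gene levels as log2 signal relative to the 75th percentile of the array. Slide and scan day followed the groups. No slide held more than 1 group, and the WT livers were alone on their slide and day, so their comparisons cannot be freed of slide and day. A slide-blocked p is the adjusted p with slide as a random block, and a day-blocked value comes from a fit with scan day as a fixed block. Scan day 2 held only DEN tumours and scan day 3 only KO tumours, so day-blocked comparisons rest mainly on the scan day 1 arrays. They draw on KO tumour mice 1 to 3 and are not independent of the fit within scan day 1. Counts of list members past the threshold were the same when adjusted over the list alone unless that count is given. The KO tumour arrays 4 to 6 shared a slide and were brighter than the rest, with 75th percentiles of 2045 to 4258 against 476 to 1357. Arrays of 1 group correlated at 0.945 to 0.979 in DEN tumours, 0.927 to 0.984 in KO tumours, 0.984 to 0.989 in KO livers and 0.965 to 0.985 in WT livers. The first principal component held 44.6% of the variance and the second 18.6%.

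Trp53, the deleted gene, gave a lower signal in both knockout groups than in the groups with intact Trp53. Its probe (mm9, chromosome 11, 69404204 to 69404263) read -3.85, -3.72, -3.39 and -3.31 in the WT livers and -6.47, -4.91, -5.91 and -5.01 in the KO livers. The DEN tumour mice gave -2.75, -2.73, -2.48, -2.65 and -2.64, and the KO tumour mice -4.60, -4.96, -4.49, -5.35 and -4.13. The means were -3.57 ± 0.26 (SD, n = 4), -5.57 ± 0.75 (n = 4), -2.65 ± 0.11 (n = 5) and -4.71 ± 0.47 (n = 5). Trp53 was well above background on 4 of 4 WT liver, 1 of 4 KO liver, 7 of 7 DEN tumour and 5 of 6 KO tumour arrays. The change was -2.002 ± 0.31 from WT to KO liver (adjusted p 0.0013, slide-blocked p 0.40) and -2.06 ± 0.28 from DEN to KO tumours (adjusted p 2.2e-05, day-blocked change -1.78). Trp53 was 0.92 ± 0.30 higher in DEN tumours than in WT livers (adjusted p 0.036, slide-blocked p 0.46). It was higher in KO tumours than in KO livers by 0.87 ± 0.30 (adjusted p 0.022), a call that ended with normexp and quantile scaling (p 0.25) and with the day block (p 0.071). The sizes of changes that involve KO livers are not measured ones, as Trp53 was above background on 1 of 4 KO liver arrays. Which exons were deleted is not given in the sources used here, so it is open whether the probe lies inside the deletion and whether the remaining signal came from cells without it.

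KO tumours were compared with DEN tumours to ask what distinguishes tumours of Trp53 knockout mice from carcinogen-induced hepatocellular carcinomas. KO tumour mice 1 and 2 had no Y-linked transcript above background, whereas all mice of the other groups did. Markers of bile duct cells were higher in KO tumours and products of mature hepatocytes lower. Epcam, a surface protein of bile duct and progenitor cells (chromosome 17, 88048972 to 88049800), rose by 6.74 ± 0.73 (adjusted p 3e-06), from -4.68 ± 1.90 in DEN tumours to 2.06 ± 1.21 in KO tumours (SD, n = 5 each). The bile duct keratins Krt19 (4.48 ± 1.04) and Krt7 (3.94 ± 0.92) and the secreted matrix protein Spp1 (3.67 ± 0.48, adjusted p 1.5e-05) also rose. In KO tumour mouse 4 neither keratin was raised, with Krt19 at -3.98 and Krt7 at -5.11 against DEN tumour means of -3.07 and -4.72. Sox9, a transcription factor of the bile duct lineage, rose by 1.08 ± 0.35 (adjusted p 0.015, slide-blocked p 0.13). Afp, a fetal liver secretory protein (chromosome 5, 90937781 to 90937840), fell by 5.82 (adjusted p 3.7e-06), and the fetal surface proteoglycan Gpc3 fell by 6.70. Albumin (Alb) fell by 2.30 (adjusted p 2.3e-04), Apoa1 by 4.03 and the urea cycle enzyme Arg1 by 3.69. With the day block these changes were 7.04 for Epcam, 5.78 for Krt19, 4.66 for Spp1, 1.49 for Sox9, -6.55 for Afp and -3.15 for Alb. That block rests mainly on scan day 1, and so on KO tumour mice 1 to 3.

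**Figure D1:**
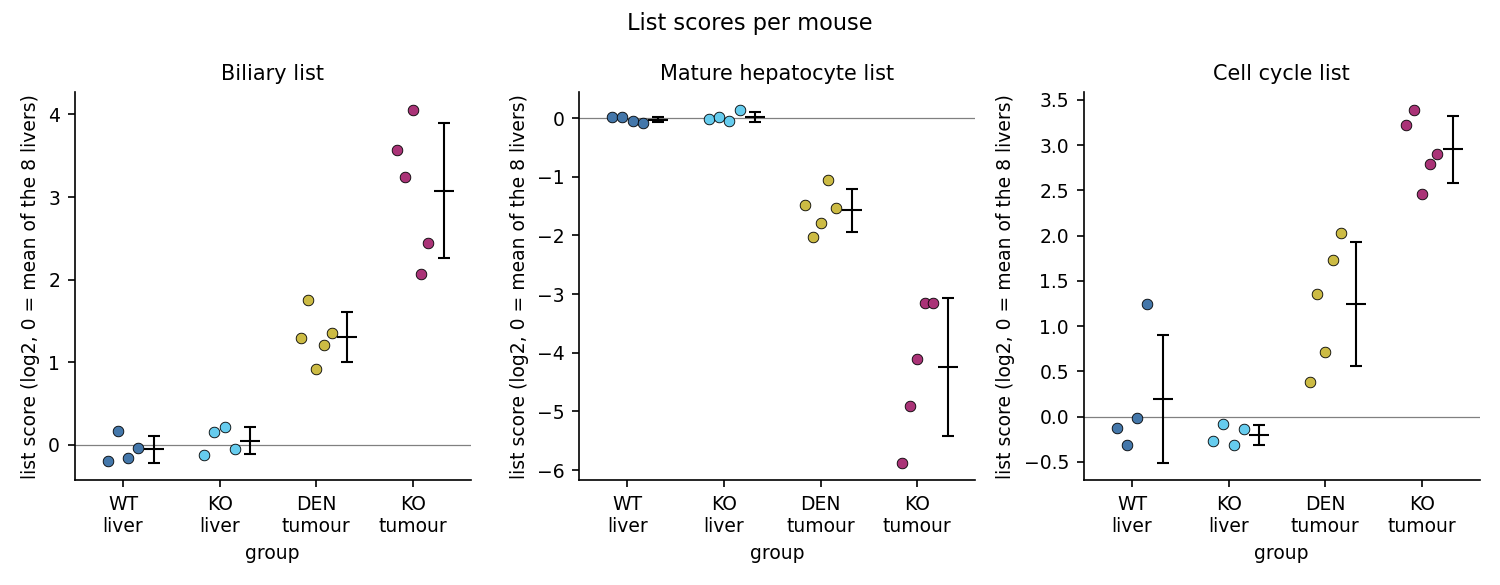
Scores of the biliary, mature hepatocyte and cell cycle lists (mean log2 signal of the list's genes, 0 = mean of the 8 livers) in WT liver, KO liver, DEN tumour and KO tumour, where points are mice and bars are mean ± SD. The biliary score was 3.08 ± 0.82 in KO tumours and 1.31 ± 0.30 in DEN tumours, and the hepatocyte score -4.24 ± 1.17 and -1.57 ± 0.36.

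Of 25 measured biliary genes, 15 rose and 0 fell in KO against DEN tumours, with a median change of 1.49 (camera adjusted p 9.9e-05, 0.389 with an estimated correlation). Of 32 mature hepatocyte genes, 27 fell and 0 rose, with a median of -2.87 (adjusted p 8.1e-06, 0.464 with an estimated correlation). Per mouse, the biliary score differed by 1.77 and the hepatocyte score by -2.67 (KO minus DEN tumour), with no overlap between the 5 and 5 mice (exact two-sided permutation p 0.00794 for each, the smallest possible with 5 and 5 mice, and 0.00794 after adjustment for both). Within scan day 1 the differences were 2.34 and -3.81 over 3 and 3 arrays without overlap, where the exact test cannot go below 0.1. All but 1 of the 11 periportal genes, which mark the hepatocytes nearest the portal vein, fell (median -4.14, adjusted p 0.0095, 0.496 with an estimated correlation), Gls2 by 4.55 and Ass1 by 3.64. Adjusted over the list alone, 1 of these rose.

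Proliferation genes were also higher. Of 34 cell cycle genes, 27 rose and 1 fell (median 1.89, adjusted p 9.6e-10, 0.389 with an estimated correlation), among them the replication helicase subunits Mcm3 (2.22 ± 0.27) and Mcm6 (1.84 ± 0.32), and the marker Mki67 rose by 3.09 ± 0.54. Tyms was the exception at -0.79 ± 0.25, a call that ended with the day block (p 0.095). Of 22 matrix and stellate genes, 19 rose and 2 fell (median 2.18, adjusted p 5.9e-07, 0.389 with an estimated correlation). Timp1, an inhibitor of matrix proteases, rose by 4.98 ± 0.57 and the proteoglycan Lum by 3.54 ± 0.48, while Fn1 (-1.18 ± 0.17) was called lower, a call that ended with normexp and quantile scaling (-0.30, p 0.076). Genes of cholesterol and fatty acid synthesis were lower (16 of 17 fell, median -1.78, adjusted p 1.1e-05, 0.389 with an estimated correlation), with Insig1 at -2.81 ± 0.23 and Lss at -3.30 ± 0.27. Of 16 NRF2 targets, which encode antioxidant enzymes, 13 fell (14 when adjusted over the list alone; median -2.01, adjusted p 0.0018, 0.464 with an estimated correlation), including Gclc (-2.42 ± 0.37) and Gstm1 (-2.85 ± 0.38).

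Shifts of 7 more lists passed with camera's preset correlation and none of these with an estimated one. The Notch list rose (5 of 13 up, 1 down; adjusted p 0.027, 0.389 estimated), with its ligand Jag1 at 2.51 ± 0.25. Another ligand, Dll1, was called higher (1.48 ± 0.30), but its other probe read -3.75. The YAP list (4 of 12 up, 1 down, adjusted p 0.048, 0.512 estimated) and the Wnt and perivenous list (6 of 15 up, 1 down, adjusted p 0.031, 0.512 estimated) also rose, and both calls ended with the day block (p 0.071 and 0.65) and the slide block (p 0.074 and 0.080). Within scan day 1 the YAP list passed (6 of 12 up, adjusted p 0.014) and the Wnt list did not (p 0.72). With normexp and quantile scaling the adjusted p was 0.078 for the Notch list, 0.20 for YAP and 0.087 for Wnt. Within these lists Tead1 rose by 2.04 ± 0.32, although another probe read -2.13, and Lef1 rose by 1.496 ± 0.23. Of 9 B and plasma cell genes 7 rose (adjusted p 0.013, 0.512 estimated), Jchain among them at 3.33 ± 1.16, but the list's day-blocked p was 0.29. Erythroid genes fell (6 of 7, adjusted p 0.027, 0.512 estimated, slide-blocked p 0.088), Hba-a1 by 4.30. Pancreatic acinar genes fell as well (4 of 6, adjusted p 0.031, 0.389 estimated), as did female-biased liver genes (6 of 10, adjusted p 0.031, 0.389 estimated, day-blocked p 0.079).

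The p53 target list did not shift between the tumour types (5 of 25 rose, 8 fell, median -0.33, adjusted p 0.59, test direction upward). Pmaip1, a pro-death BH3 protein, rose by 3.61 ± 0.49, whereas Perp (-1.18 ± 0.23), Btg2 (-1.88 ± 0.42) and the cell cycle inhibitor Cdkn1a (-1.23 ± 0.39, adjusted p 0.013) fell. The call for Cdkn1a ended with the day block (p 0.060) and the slide block (p 0.23), and Mdm2 did not pass (-0.35 ± 0.22, adjusted p 0.18). The oncofetal list did not shift (1 of 18 rose, 5 fell, adjusted p 0.59), with Cd44 up by 3.46 ± 0.34 and Afp and Gpc3 down. The macrophage (4 of 11 up, 2 down, median 0.74, mean -0.09, adjusted p 0.29), T and NK cell (3 of 13 up, 5 down, adjusted p 0.56) and neutrophil lists (1 of 10 up, 1 down, adjusted p 0.58) moved both ways or little. The same held for the ERK output (4 of 19 up, 5 down, adjusted p 0.56) and glycolysis lists (4 of 16 up, 6 down, median -0.32, mean 0.26, adjusted p 0.56). The endothelial (0 of 10 up, 4 down, median -0.43, mean -1.01, adjusted p 0.52), interferon (2 of 18 up, 11 down, median -0.87, adjusted p 0.12) and male-biased lists (0 of 8 up, 4 down, median -1.79, or -1.48 with bounds, adjusted p 0.35) had more members lower, but their shifts did not pass. Adjusted over the list alone, 4 Notch and 3 YAP genes rose, 4 oncofetal, 4 ERK output, 3 endothelial and 3 male-biased genes fell, and 0 neutrophil genes passed.

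**Figure D2:**
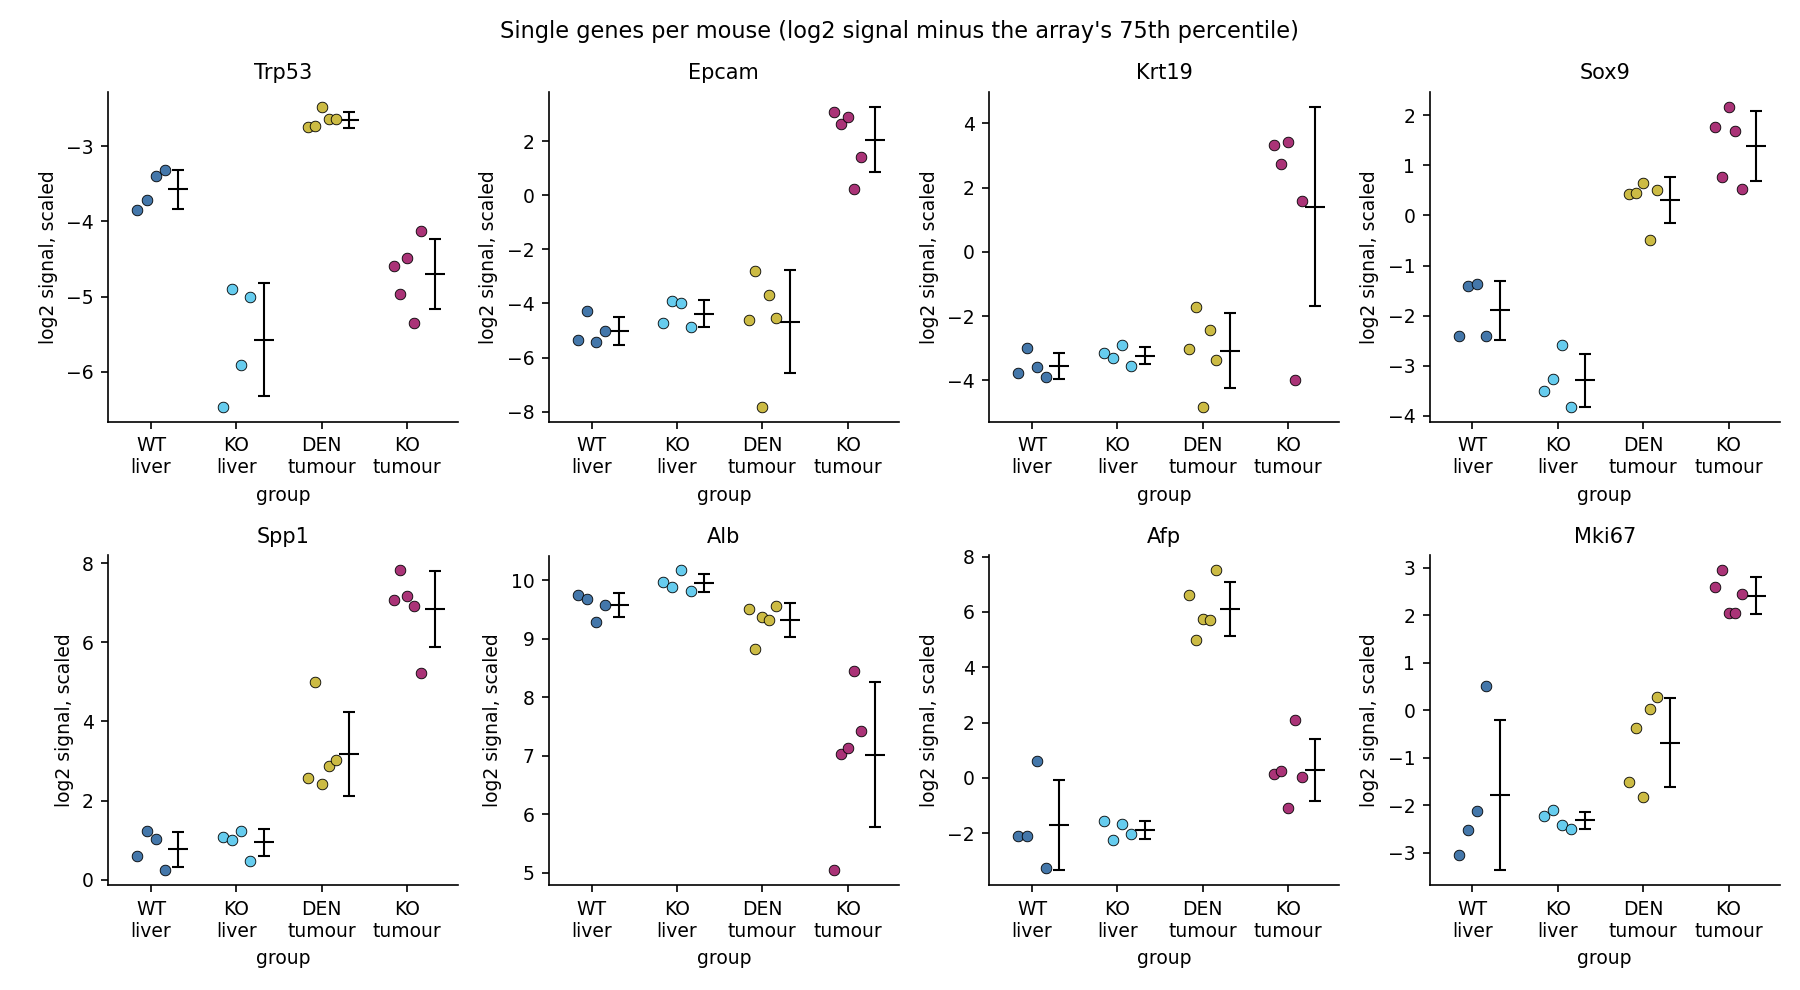
Log2 signal minus the 75th percentile of the array for Trp53, Epcam, Krt19, Sox9, Spp1, Alb, Afp and Mki67 in WT liver, KO liver, DEN tumour and KO tumour, where points are mice and bars are mean ± SD. Spp1 averaged 6.84 ± 0.97 in KO tumours and 3.18 ± 1.05 in DEN tumours, and Krt19 was -3.98 in KO tumour mouse 4 and 1.59 or higher in the other 4 KO tumour mice.

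Among the genes that rose furthest in KO over DEN tumours were Reg3g (12.06 ± 0.65) and Reg3b (11.50 ± 1.55), secreted lectins of 1 gene family whose probes may share signal. Gp2 rose by 11.86 ± 0.75 and Guca2b by 9.51 ± 0.83, and Dmbt1, a mucin-like glycoprotein, was at least 1271-fold higher. For a gene with no probe above background on any array of the lower group, such a fold is a lower bound against the lowest signal well above background. Reg3g and Reg3b were above background on 1 of 7 DEN tumour arrays, Gp2 on 4 and Guca2b on 5, so the sizes for Reg3g and Reg3b are not measured ones. Gldn (-10.00 ± 0.996, above background on 2 of 6 KO tumour arrays), the steroid enzyme gene Akr1c18 (-7.59 ± 0.79) and Erich4 (-7.50 ± 0.99) were among the genes that fell furthest, and Pnpla5 was at least 28.7-fold lower.

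In all, 13578 of 23702 genes differed between KO and DEN tumours, 4701 higher and 8877 lower (65.4% lower), of which 3394 and 6647 differed at least 2-fold. The split depended on the scaling. With normexp and quantile scaling 5961 genes were higher and 6700 lower (52.9% lower), and the median of all genes moved from -0.33 to -0.04, which quantile scaling brings about by making the arrays alike. With scaling on the median of probes above background 62.7% were lower, and with the authors' values 65.0%. With the day block 4707 were higher and 6801 lower, within scan day 1 the counts were 4881 and 7140, and with the slide block 9215 genes passed.

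KO tumours were compared with KO livers to ask what changed from knockout liver to tumour. The transcription factor Sox9 (chromosome 11, 112648809 to 112648868) rose by 4.68 ± 0.37 (adjusted p 9.1e-08), Spp1 by 5.90 ± 0.51 (2e-07) and Epcam by 6.43 ± 0.78 (4.3e-06). Krt19 rose by 4.63 ± 1.10 (adjusted p 0.0022), and Krt7 was at least 15.1-fold higher on the mean of the mice. KO tumour mouse 4 shared neither rise, with Krt19 at -3.98 and Krt7 at -5.11 against KO liver means of -3.22 and -5.47. Mki67 rose by 4.73 ± 0.57, Timp1 by 8.18 ± 0.60 and the imprinted growth regulator H19 by 6.38 ± 1.36, although a second H19 probe read -0.12. Alb fell by 2.94 (adjusted p 3.5e-05), the tyrosine-degrading enzyme Hpd by 6.04 (1.2e-07) and Ass1 by 5.17. The glutamine synthetase gene Glul fell by 2.96 (slide-blocked p 0.081). Afp rose by 2.16 ± 0.69 (adjusted p 0.015, slide-blocked p 0.19). Krt20 (at least 1450-fold), Gp2 (at least 2599-fold), Reg3g (at least 974-fold) and the protease Mmp7 (at least 558-fold higher) were among the most raised, and Sult2a7 (-10.46 ± 0.81, above background on 1 of 6 KO tumour arrays), Hamp2 (-10.02 ± 0.67) and Cyp2b13 (-9.69 ± 0.91) among the most lowered. Cyp2b13 is a female-biased gene that was also higher in KO than in WT livers, as given further on.

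Biliary genes rose in KO tumours over KO livers (19 of 25 up, 1 down, median 3.67, camera adjusted p 1.4e-07, 0.151 with an estimated correlation), the exception being the water channel gene Aqp1 at -1.46 ± 0.29. Hepatocyte genes fell (31 of 32, median -4.07, adjusted p 6.8e-12, 0.184 estimated), as did periportal genes (9 of 11, adjusted p 0.0020, 0.309 estimated) and Wnt and perivenous genes (12 of 15 down, 1 up, adjusted p 0.0067, 0.361 estimated). All 17 genes of cholesterol and fatty acid synthesis fell (median -2.55, adjusted p 1.6e-09, 0.0634 estimated), among which Insig1 fell by 3.32. Cell cycle genes rose (31 of 34 up, 1 down, 32 up when adjusted over the list alone, median 3.65, or 3.31 with bounds, adjusted p 3.4e-14, 0.184 estimated), Mcm2 by 3.43 ± 0.28. Tpx2, the member called lower (-1.27 ± 0.49), had another probe at 3.48. Matrix genes rose (18 of 22 up, 1 down, adjusted p 1.0e-07, 0.234 estimated), with the collagen gene Col4a1 at 3.60 ± 0.43. Oncofetal genes rose too (12 of 18 up, 1 down, median 1.83, adjusted p 3.6e-04, 0.05002 estimated), Ly6d by 6.00 ± 0.54 and Golm1 by 4.05 ± 0.38.

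The pathway lists rose in part. ERK output genes rose (8 of 19 up, 2 down, 9 up over the list alone, median 0.95, or 0.75 with bounds, adjusted p 0.0037, 0.195 estimated), with Etv4 at 4.79 ± 0.45. Notch (6 of 13 up, 1 down, adjusted p 0.0067, 0.195 estimated) and YAP genes (8 of 12 up, 1 down, adjusted p 0.0067, 0.309 estimated) rose, Jag1 by 3.08 ± 0.27 and Ajuba by 3.21 ± 0.21. The p53 target list rose although both groups were Trp53 knockout (11 of 25 up, 5 down, median 0.38, adjusted p 0.022, 0.184 estimated), but its day-blocked p was 0.10. Pmaip1 rose by 5.16 ± 0.52 and Tnfrsf10b by 3.91 ± 0.33, and Cdkn1a was at least 8.46-fold higher, whereas its other probes read -0.05 and 0.37 on the log2 scale. B and plasma cell genes (4 of 9 up, median 1.58, or 1.54 with bounds, adjusted p 0.010, 0.463 estimated, day-blocked p 0.24) rose, and erythroid genes (5 of 7 down, adjusted p 0.022, 0.462 estimated, slide-blocked p 0.063) fell. All 10 female-biased liver genes fell (median -7.68, adjusted p 9.3e-07, 0.05002 estimated), while the male-biased list did not pass (3 of 8 down, adjusted p 0.28). The female-biased fall rests on high KO livers, with a mean score of 3.68 there, -3.49 in KO tumours and -3.68 in WT livers.

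The NRF2 list did not pass (2 of 16 up, 9 down, 10 over the list alone, adjusted p 0.10), but it was called lower with the day block (p 0.013) and within scan day 1 (p 0.0025). These are not separate supports, since both rest on the scan day 1 tumours and gave the same median (-2.29). Both leave out KO tumour mouse 4, whose NRF2 score was 0.61 against -1.32 to -0.66 in the other KO tumour mice. No shift passed for the glycolysis (7 of 16 up, 5 down, median -0.31, mean 0.74, adjusted p 0.36), interferon (6 of 18 up, 3 down, adjusted p 0.30), T and NK (4 of 13 up, 1 down, 0 down over the list alone, adjusted p 0.063), neutrophil (4 of 10 up, 1 down, median 1.04, or 0.32 with bounds, adjusted p 0.11) or pancreatic lists (1 of 6 up, 2 down, adjusted p 0.28). Among endothelial genes (2 of 10 up, 4 down, 5 over the list alone, adjusted p 0.78) the sinusoidal markers Stab2 (-3.35 ± 0.64) and Clec4g (-6.08 ± 0.67) fell and Emcn rose (1.84 ± 0.32). Among macrophage genes (5 of 11 up, 6 over the list alone, and 5 down, median 0.91, mean -0.36, adjusted p 0.43), Cd14 (4.77 ± 0.42) and Lyz2 (4.20 ± 0.46) rose, and the Kupffer cell genes Cd5l (-4.39 ± 0.99, slide-blocked p 0.15) and Clec4f (-4.67 ± 1.18, slide-blocked p 0.22) fell. In all, 12093 genes differed, 5107 higher and 6986 lower (57.8% lower), of which 4175 and 4888 by at least 2-fold. With normexp and quantile scaling 5977 were higher and 5736 lower (49.0% lower) and the median of all genes moved from -0.22 to -0.01, while without a filter 5117 were higher and 11528 lower. The count was 12426 with the day block and 6682 with the slide block.

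DEN tumours were compared with WT livers to ask the same of tumours with intact Trp53. Afp rose by 7.82 ± 0.69 (adjusted p 1.6e-06, slide-blocked p 8.9e-04), the fetal liver antigen Ly6d by 6.80 ± 0.54 and H19 by 6.76 ± 1.36 (slide-blocked p 0.099). Cdkn1a rose by 4.43 ± 0.42 (adjusted p 2.8e-06, slide-blocked p 0.0056), from -4.82 ± 0.38 in WT livers (n = 4) to -0.39 ± 0.98 in DEN tumours (n = 5). Sox9 rose by 2.20 ± 0.37 (adjusted p 5.5e-04) and Spp1 by 2.41 ± 0.51 (adjusted p 0.003), with slide-blocked p of 0.092 and 0.16. Krt19 (0.48 ± 1.10), Krt7 (0.24 ± 0.97), Epcam (0.34 ± 0.78), Alb (-0.26 ± 0.44) and Mki67 (1.11 ± 0.57) did not pass, although Mki67 passed with array weights (adjusted p 0.017). Krt7 and Epcam were above background on 1 of 4 WT liver arrays. Glul, a Wnt target of the hepatocytes near the central vein, fell by 4.32 (adjusted p 8e-05, slide-blocked p 0.11). The biliary tetraspanin Tspan8 (8.33 ± 0.55) and Bex1 (9.61 ± 0.95), the latter above background on 1 of 4 WT liver arrays, and Kif5c (at least 123-fold higher) were among the most raised. The male-biased genes Hsd3b5 (-11.10 ± 1.36, slide-blocked p 0.065) and Elovl3 (-10.19 ± 1.12, slide-blocked p 0.027) fell furthest. Pax2 was called at -8.10 ± 1.03, but its other probes, dimmer, read 0.83 and 0.09.

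Oncofetal genes rose in DEN tumours (12 of 18 up, median 4.48, camera adjusted p 3.4e-09), and this was the only list call of the comparison that held with an estimated correlation (0.00142). ERK output genes rose (13 of 19, 14 over the list alone, median 1.61, or 1.49 with bounds, adjusted p 1.9e-07, 0.0509 estimated), with the feedback inhibitors Spry1 at 2.13 ± 0.22 and Spred1 at 1.95 ± 0.23, another Spred1 probe reading -0.25. Interferon response genes rose (13 of 18, 14 over the list alone, median 1.65, adjusted p 5.9e-08, 0.131 estimated), Oas1a by 3.19 ± 0.30 and Ifi44 by 2.93 ± 0.36. The p53 targets rose (9 of 25 up, 1 down, median 0.44, adjusted p 8.5e-04, 0.0681 estimated), with Psrc1 at least 16.4-fold higher. Cell cycle (10 of 34 up, 1 down, 16 up over the list alone, median 1.10, adjusted p 1.6e-05, 0.461 estimated) and biliary genes (8 of 25 up, 1 down, 9 up over the list alone, median 0.64, adjusted p 7.5e-04, 0.366 estimated) rose, with Mcm2 at 1.58 ± 0.28 (slide-blocked p 0.12) and Prom1 at 5.84 ± 0.43.

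NRF2 targets rose (5 of 16 up, 1 down, adjusted p 0.0093, 0.461 estimated), Cbr3 by 5.89 ± 0.56, as did matrix genes (7 of 22, 8 over the list alone, median 1.02, or 0.87 with bounds, adjusted p 0.0015, 0.461 estimated). Without DEN tumour mouse 2 the median of the matrix list was 0.58 (adjusted p 0.021). Calls for the Notch (4 of 13 up, 1 down, median 0.98, or 0.48 with bounds, adjusted p 0.031, 0.366 estimated) and neutrophil lists (3 of 10 up, median 1.52, or 0.39 with bounds, adjusted p 0.045, 0.461 estimated) ended with the slide block (p 0.062 and 0.071). Without DEN tumour mouse 1 the neutrophil list had an adjusted p of 0.18, and without DEN tumour mouse 2 the Notch list 0.074. Adjusted over the list alone, 7 Notch genes rose and 2 fell. Hepatocyte genes fell (9 of 32, 10 over the list alone, median -1.06, adjusted p 1.1e-05, 0.447 estimated), among them the bile acid enzymes Cyp7a1 (-6.32 ± 1.04, slide-blocked p 0.20) and Cyp8b1 (-6.33 ± 0.72, slide-blocked p 0.053). Wnt and perivenous genes fell (10 of 15, 11 over the list alone, adjusted p 1.9e-07, 0.0957 estimated). Male-biased genes fell (6 of 8, 7 over the list alone, median -5.62, adjusted p 6.4e-07, 0.0957 estimated) and female-biased genes rose (6 of 10, 7 over the list alone, median 2.84, adjusted p 1.9e-04, 0.078 estimated).

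No shift passed in DEN tumours for periportal (0 of 11 changed, adjusted p 0.37), YAP (2 of 12 up, 1 down, adjusted p 0.32), glycolysis (5 of 16 up, adjusted p 0.091) or cholesterol synthesis genes (2 of 17 up, 4 down, adjusted p 0.16), although Fasn fell by 1.65 (slide-blocked p 0.15). Nor did it for endothelial (3 of 10 up, adjusted p 0.11), macrophage (3 of 11 up, median -0.09, mean 0.16, adjusted p 0.37), T and NK (1 of 13 up, 0 over the list alone, adjusted p 0.083), B and plasma (0 of 9, adjusted p 0.20), erythroid (4 of 7 up, 1 down, adjusted p 0.32) or pancreatic genes (1 of 6 up, median 0.21, or 0.05 with bounds, adjusted p 0.36). Adjusted over the list alone, 4 YAP genes rose and 2 fell, 2 cholesterol synthesis genes rose and 6 fell, 4 endothelial genes rose, and 4 erythroid genes rose and 2 fell. In all, 5090 genes differed, 2502 higher and 2588 lower, of which 1827 and 1517 by at least 2-fold. With the slide block 422 genes passed, 298 higher and 124 lower.

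The changes from liver to tumour overlapped between the models. Of the genes raised in each, 1291 were shared against 539 expected (odds ratio 4.86, Fisher's exact p 9.8e-274), and 1776 lowered genes were shared against 763 expected (odds ratio 6.68). Opposite calls were fewer than expected, 146 genes up in KO and down in DEN tumours against 558, and 304 the other way against 737. The log2 changes correlated across genes, which are not independent replicates, with a Pearson r of 0.41 and a Spearman rho of 0.35. No array served in both comparisons.

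**Figure D3:**
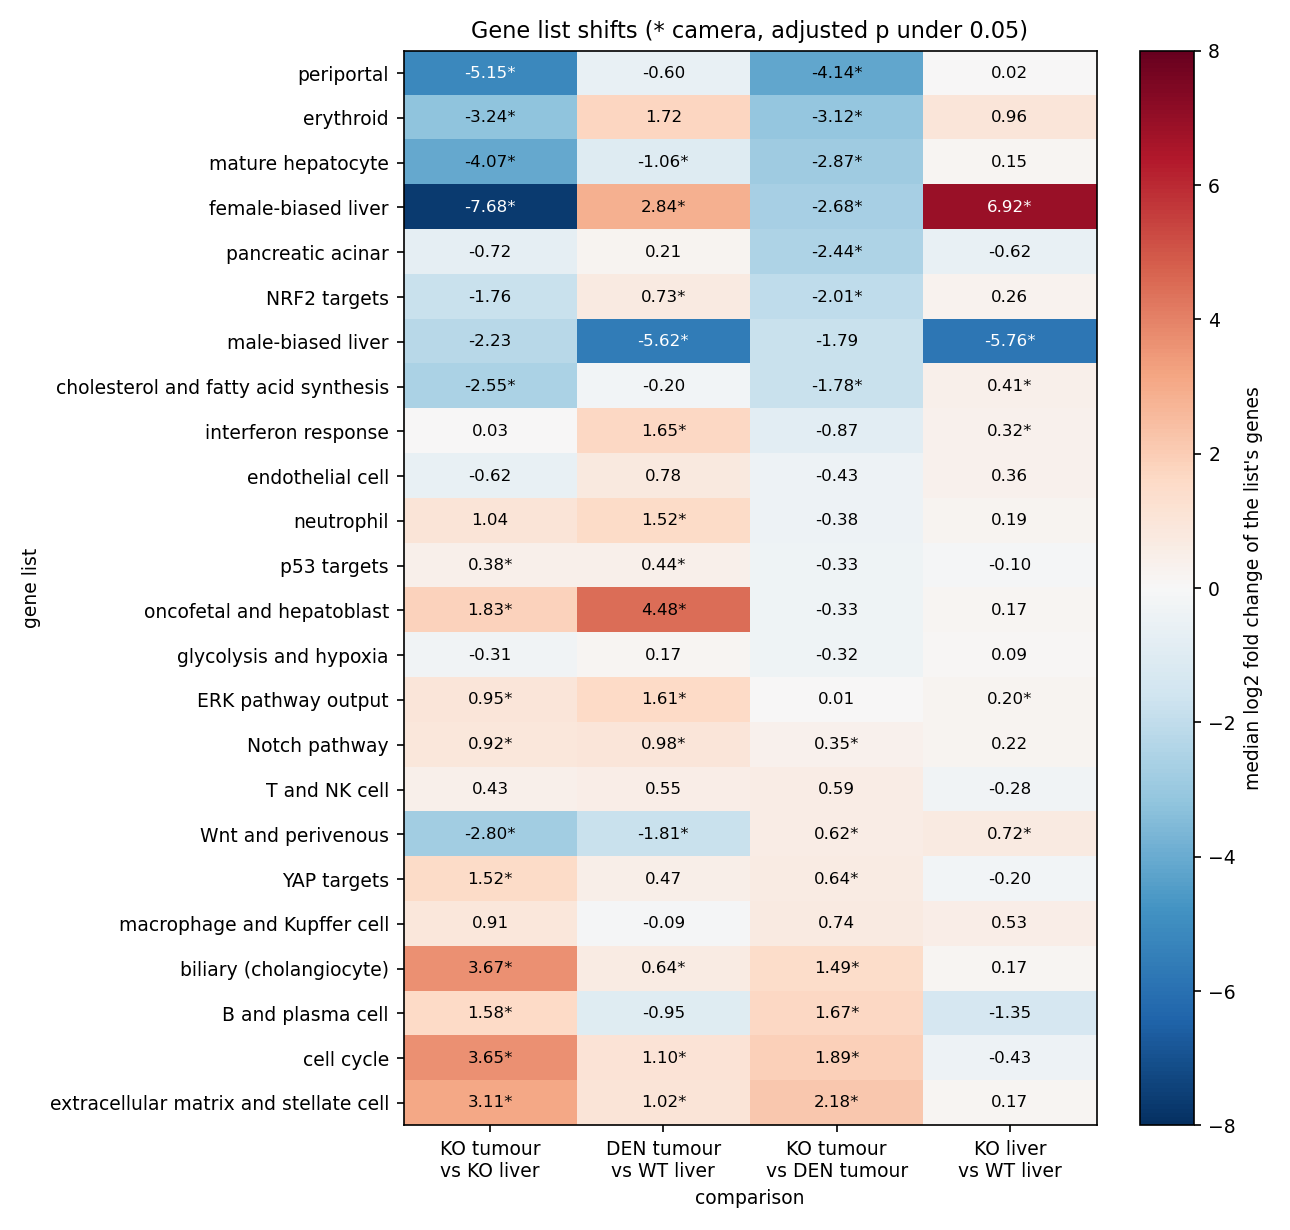
Median log2 fold change of the genes of each of 24 fixed lists in the 4 comparisons of groups, with an asterisk where the camera adjusted p was below 0.05. The oncofetal list had a median of 4.48 in DEN tumours against WT livers and 1.83 in KO tumours against KO livers.

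The difference between those tumour effects (KO tumour minus KO liver, less DEN tumour minus WT liver) asks whether tumours of Trp53 knockout and wild-type mice departed from their own liver differently. Epcam rose more in the KO model, by 6.09 ± 1.10 (adjusted p 8.7e-04, slide-blocked p 0.055), as did Spp1 (3.49 ± 0.72, slide-blocked p 0.11), Sox9 (2.48 ± 0.53, slide-blocked p 0.13) and Mki67 (3.62 ± 0.81, slide-blocked p 0.16), while Krt19 did not pass (4.15 ± 1.56, adjusted p 0.053). The size for Epcam is not a measured one, since it was above background on 3 of 4 KO liver and 1 of 4 WT liver arrays. Part of the difference for Sox9 lies in the livers, with means of -3.29 in KO and -1.90 in WT livers. Its means were 1.38 in KO and 0.31 in DEN tumours. The difference was -5.66 ± 0.98 for Afp (slide-blocked p 0.052) and -2.68 ± 0.62 for Alb (slide-blocked p 0.084). Gp2, Reg3g and Dmbt1 were called higher, and the sulfotransferase gene Sult2a2 lower, but no size is given, since no array of 1 of the liver groups had them above background. Sult2a2 rests on the high level in KO livers given further on. The same limit leaves the difference for Cdkn1a open. Trp53, above background on 1 of 4 KO liver arrays, did not pass (-0.05 ± 0.42, adjusted p 0.94).

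Lists with higher tumour effects in the KO model were biliary (9 of 25 up, 2 down, adjusted p 0.0011), cell cycle (23 of 34 up), matrix (12 of 22 up, 2 down), YAP (3 of 12 up), B and plasma cell (6 of 9 up) and male-biased genes (5 of 8 up). Lower ones were hepatocyte (24 of 32 down), periportal (6 of 11 down), NRF2 (12 of 16 down), cholesterol synthesis (15 of 17 down), interferon (10 of 18 down), erythroid (4 of 7 down), pancreatic (2 of 6 down) and female-biased genes (10 of 10 down). Adjusted over the list alone, 14 biliary genes were up and 3 down, 24 cell cycle, 14 matrix, 2 YAP and 8 B and plasma cell genes up, and 7 periportal, 13 NRF2, 16 cholesterol synthesis, 5 erythroid and 3 pancreatic genes down. Only the female-biased list kept its call with an estimated correlation (adjusted p 0.00528); the others had 0.0973 (cholesterol synthesis), 0.384 (interferon) or 0.337. The p53 target (median -0.14), oncofetal (-1.10, adjusted p 0.13), Wnt (0.30), ERK (-0.19), Notch (0.14), glycolysis (-0.30), endothelial (-0.72), macrophage (-0.39), T and NK (-0.13) and neutrophil lists (-0.59) did not pass. In all, 7321 genes differed, 3001 higher and 4320 lower, 2736 and 3705 of them by at least 1 log2 unit. With the slide block 798 passed, and with normexp and quantile scaling 48.4% of calls were lower and the median of all genes moved from -0.24 to -0.01.

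KO livers were compared with WT livers to ask what differed between the genotypes in liver without tumour. The p53 target list did not shift (2 of 25 rose, 3 up and 2 down over the list alone, median -0.10, or 0.00 with bounds, mean 0.04, adjusted p 0.36). Cdkn1a was -0.80 ± 0.44 (adjusted p 0.29), above background on 0 of 4 KO and 2 of 4 WT liver arrays, and Mdm2 was 0.25 ± 0.24 (adjusted p 0.59). Trp53inp1 (1.26 ± 0.35) and Rrm2b (1.15 ± 0.31) rose, with slide-blocked p of 0.84 and 0.74, and another Trp53inp1 probe read -0.44. Alb (0.38 ± 0.46), Afp (-0.17 ± 0.73), Krt19 (0.33 ± 1.16), Epcam (0.65 ± 0.82) and Mki67 (-0.52 ± 0.60) did not pass. Sox9 fell by 1.40 (adjusted p 0.036, slide-blocked p 0.81).

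The largest differences between KO and WT liver lay in genes whose level differs between male and female livers. Of 10 female-biased genes, 9 rose, and 10 when adjusted over the list alone (median 6.92, adjusted p 2.6e-21, 1.55e-04 with an estimated correlation). Of 8 male-biased genes, 6 fell, and 7 over the list alone (median -5.76, adjusted p 2.4e-08, 0.145 estimated). The sulfotransferase genes Sult2a2 (chromosome 7, 14364926 to 14364985) and Sult2a6 were at least 6388-fold and 5572-fold higher, with slide-blocked p of 2.1e-04 and 0.016, but their probes may share signal. Cyp2b13 rose (8.53 ± 0.96, above background on 2 of 4 WT liver arrays), with a slide-blocked p of 0.13. The steroid enzyme gene Hsd3b5 was at least 1666-fold lower (slide-blocked p 0.25) and the transporter gene Slco1a1 at least 128-fold lower (slide-blocked p 0.074). Per mouse, the female-biased score was 3.68 ± 0.21 in KO and -3.68 ± 0.42 in WT livers, and the male-biased score -2.94 ± 0.39 and 2.94 ± 0.51. Both separated the groups (exact two-sided permutation p 0.0286, the smallest for 4 against 4). DEN tumours had a female-biased score of -0.70 ± 0.78 and KO tumours one of -3.49 ± 0.77.

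**Figure D4:**
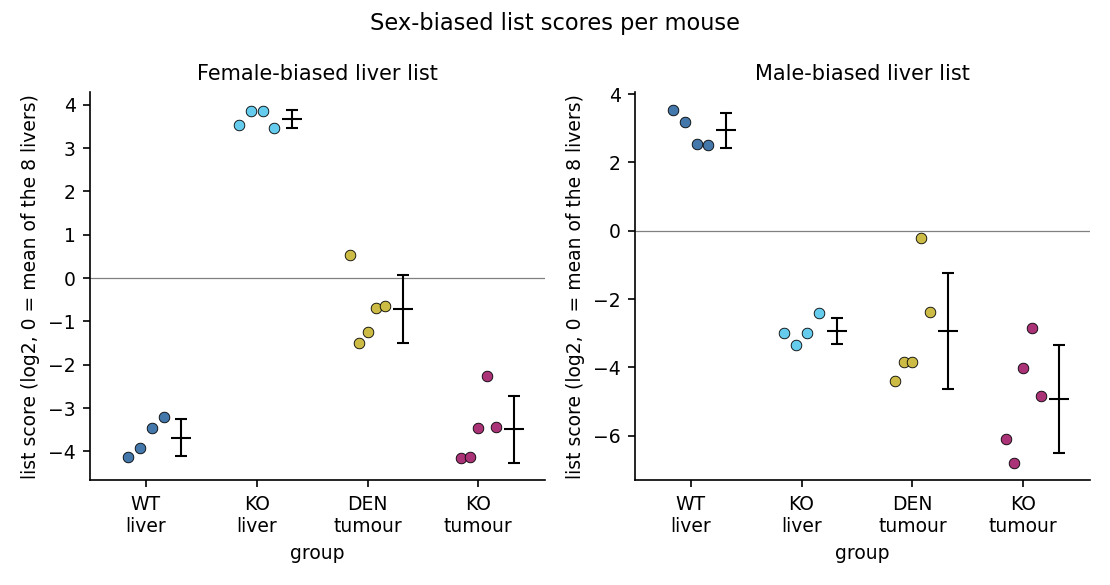
Scores of the female-biased and male-biased liver lists (mean log2 signal of the list's genes, 0 = mean of the 8 livers) in WT liver, KO liver, DEN tumour and KO tumour, where points are mice and bars are mean ± SD. KO livers averaged 3.68 on the female-biased list against -3.68 in WT livers.

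Y-linked transcripts were as high in KO livers as in WT livers, with a mean of 0.70 and 0.71 for Ddx3y. In KO tumours 1 and 2 Ddx3y was -8.85 and -9.04 and not above background, and an Xist probe read -1.29 and -1.81. That probe was not above background on the other 19 arrays, while a second Xist probe was above background on these 2 arrays and on the 4 DEN tumour arrays of 1 slide. The list of Y-linked genes and Xist, with 4 members measured, was not tested, and 3 of its members were lower in KO tumours than in KO livers. That fall mixes KO tumour mice with and without Y-linked transcripts above background.

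Smaller shifts in KO livers were a rise of cholesterol and fatty acid synthesis genes (3 of 17 up, 6 over the list alone, median 0.41, adjusted p 2.5e-04, 0.499 with an estimated correlation), and of Wnt and perivenous genes (1 of 15, adjusted p 0.018, 0.782 estimated), with the ammonium transporter Rhbg at 1.80 ± 0.41. Interferon genes (1 of 18, 3 over the list alone, adjusted p 0.015, 0.782 estimated) and ERK output genes (4 of 19, 5 over the list alone, adjusted p 0.048, 0.702 estimated) rose as well. Both calls ended without WT liver 1 (p 0.18 and 0.17), the interferon call also without KO liver 1 (p 0.063), and Ccnd1, a member of the ERK list at 2.26 ± 0.47, had a slide-blocked p of 0.65. Biliary (1 of 25 up, 2 down, 3 down over the list alone, median 0.17, adjusted p 0.32), hepatocyte (0 of 32, median 0.15, adjusted p 0.40), oncofetal (3 of 18 up, adjusted p 0.14) and cell cycle genes (0 of 34 up, 2 down, median -0.43, or -0.37 with bounds, adjusted p 0.29) did not shift, nor did the other 13 lists. Adjusted over the list alone, 1 cell cycle gene fell, and 2 erythroid genes rose and 1 fell. In all, 2016 genes differed, 434 higher and 1582 lower (78.5% lower), of which 263 and 1400 by at least 2-fold. The count fell to 999, 866, 1108 and 1090 without KO liver 1, 2, 3 and 4, and to 660 and 903 without WT liver 3 and 4. With normexp and quantile scaling 608 were higher and 1155 lower (65.5% lower). With the slide block 11 genes passed, 7 higher and 4 lower, against 5499 at an unadjusted p under 0.05 in the fit without it.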

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

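Chosen after the result was seen were the tests of the sex of the KO livers, of the scan day that KO livers share with DEN tumour arrays, of slide and scan day for the biliary difference, of a lower share of hepatocytes, and of the pair of KO tumour mice that express Xist. The comparisons, lists, named-gene rule and main processing were fixed before the data were examined. The remaining tests were written before their own results were seen, but those on the KO livers and on the share of lower genes were thought of once the pattern itself was known.

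Other splits of the mice into groups of the same sizes were used to ask whether chance can account for the counts of changed genes. For KO tumour against KO liver only the real split, 1 of 100, called as many genes (12093), so chance is argued against. The highest other split called 11182 and moved KO tumour mouse 4 alone to the KO livers, and the next, with KO tumour mouse 5 moved, called 7943. So many calls in a split point to a structure of the samples, here near the real groups with KO tumour mouse 4 apart from the other KO tumours. The only array of that mouse was marked for evaluation, so array quality cannot be told apart from the tumour here. For KO against DEN tumours it was again only the real split, 1 of 100 (13578 genes, highest other 6839), and for DEN tumour against WT liver 1 of 100 (5090, highest other 2983, with DEN tumour mouse 4 moved to the WT livers). For KO liver against WT liver it was 1 of 35 (2016, highest other 2), the smallest share that 4 against 4 mice allow. For the difference of the tumour effects it was 1 of 100 (7321, highest other 1511). Chance is argued against in these too, but such shares do not exclude it. This says nothing about slide and day, which follow the groups.

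Genes with female-biased expression in liver were higher, and male-biased ones lower, in KO livers than in WT livers, although nothing in the labels separates the sexes. Female KO mice are argued against, since the mean of the Y-linked Ddx3y and Eif2s3y differed by 0.0125 and no KO liver array had Xist above background by the probe that stood for the gene. DEN tumour arrays of scan day 1, the day of the KO livers, exceeded those of scan day 2 by 0.130 in the female-biased score. That is 1.76% of the difference between the livers. Within DEN tumour mice 4 and 5, which had a tumour on both days, the difference was -0.98 and -1.16. A rise on scan day 1 over scan day 2 is thus argued against in DEN tumours. No DEN tumour array shared the day of the WT livers, so a shift between the days of the livers could not be tested. A change in the pattern of growth hormone, which sets the sex bias of liver genes, stays open as a candidate explanation: 2 of its 3 regulators passed in the direction it needs, Cux2 at 3.94 ± 0.79 (above background on 1 of 4 WT liver arrays) and Bcl6 at -1.80 ± 0.47, and Tox did not (1.07 ± 0.35, adjusted p 0.070), but these genes are sex-biased in liver themselves and so do not set it apart from other sources of the pattern. Slide and day of the WT livers cannot be told apart from the genotype, and housing or age, not given in the sources used here, were not tested.

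Biliary genes were higher and hepatocyte genes lower in KO tumours than in DEN tumours, and their changes against the own liver differed the same ways (biliary list 1.86, adjusted p 0.0011; hepatocyte list -3.13, adjusted p 4.0e-07; both 0.337 with an estimated correlation). Scan day is argued against as the whole cause, since within scan day 1 the biliary score still differed by 2.34 with no overlap of 3 and 3 arrays (exact permutation p 0.100, the smallest possible), against 1.77 over all mice, and so is the pair of KO tumour mice that express Xist, since without them the difference was 1.55. Slide cannot be told apart from the group, as each slide held 1 group and the score differed by 1.37 between the KO tumour slides. A lower share of hepatocytes, which raises all other cell types alike, is argued against as the whole cause for the matrix and biliary lists. List medians were -0.43 for endothelial cells, 0.74 for macrophages (mean -0.09), 1.67 for B and plasma cells and 2.18 for matrix. Per mouse the matrix minus endothelial score differed by 3.18 and the biliary minus endothelial score by 2.78 (exact permutation p 0.00794 for each). The B and plasma cell gap differed by 2.86 (exact permutation p 0.0159), but the macrophage gap did not pass (0.92, exact permutation p 0.103). The endothelial list includes the sinusoidal marker Clec4g, which fell further than Pecam1, so part of each gap may lie in such genes. What stays open is a change of the tumour cells toward the bile duct lineage or more bile duct and matrix cells in the tissue, which may both fit the combined diagnosis in the labels, as well as the DEN treatment, which only 1 tumour group received.

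More genes were lower than higher in KO tumours than in DEN tumours (65.4% of calls). Whether the scaling is the source cannot be told apart from a real difference: the share was 52.9% with normexp and quantile and 54.5% with quantile scaling, which make the arrays alike and so bring it toward 50% whatever its source, but 62.7% with the median of probes above background and 65.0% with the authors' values. The brighter slide of KO tumour mice 4 and 5 is argued against, with 61.9% without them, and so are genes near the background, with 64.5% among the brighter 50% of genes and 66.2% among the dimmer 50%. A real drop of many transcripts in KO tumours was not tested, since every scaling sets a level for the whole array.

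The tumour effect differed between the models, by the test of the difference itself, in 12 more lists at the preset correlation, of which only the female-biased list passed with an estimated one (0.00528, the others 0.0973 to 0.384). These were cell cycle (2.12, adjusted p 8.8e-11), periportal (-3.87, 0.0017), YAP (0.86, 0.0076), NRF2 (-2.21, 1.5e-04), cholesterol and fatty acid synthesis (-2.15, 1.8e-09), interferon (-1.16, 0.0040) and matrix (2.30, 2.6e-05). The others were B and plasma cell (2.99, 0.0011), erythroid (-3.33, 0.0040), pancreatic acinar (-1.69, 0.048), male-biased (4.63, 0.0058) and female-biased genes (-10.33, 8.8e-11). Among the genes always named, the effect differed for Alb (-2.68, adjusted p 0.0045), Afp (-5.66, 6.6e-04), Sox9 (2.48, 0.0026), Epcam (6.09, 8.7e-04), Spp1 (3.49, 0.0022) and Mki67 (3.62, 0.0036). Krt7 was called too (4.45, 0.023), but that size is not a measured one, since Krt7 was above background on 0 of 4 KO liver and 1 of 4 WT liver arrays. The same holds for the size for Epcam, with 3 of 4 and 1 of 4. The female-biased difference rests mostly on the KO livers described above. For the male-biased list the WT livers stood apart, with a mean score of 2.94 against -2.94 in KO livers, -2.94 in DEN tumours and -4.92 in KO tumours. The WT livers were alone on their slide and day.

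In 9 of 156 groups a mouse lay far from the others of its group by Dixon's test, about the 5% (1 in 20) that chance gives. KO tumour mouse 4 had the highest oncofetal score (3.82, others 2.04 to 2.52) and the lowest Krt19 (-3.98, others 1.59 to 3.41). Among DEN tumour mice, mouse 1 had a neutrophil score of 2.88 (others 0.54 to 1.18) and mouse 2 a Spp1 level of 5.01 (others 2.41 to 3.02). Krt7 was -7.08 in DEN tumour mouse 3 (others -4.52 to -3.60) and Sox9 -0.49 in DEN tumour mouse 4 (others 0.42 to 0.65). KO liver 1 had a T and NK cell score of 0.27 (others -0.26 to -0.20). WT liver 3 had a glycolysis score of -0.24 (others 0.02 to 0.04), and WT liver 4 a B and plasma cell score of 2.98 (others -0.35 to 0.01).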

How the results depend on the processing

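Chosen after the data were seen were the fits within scan day 1, without the KO tumour mice that express Xist, without the KO tumour mice of slide 5, without the arrays marked for evaluation and without the sex-biased and sex-linked lists. The other alternatives were chosen before the data were examined, and none planned for a result was left unrun.

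Over 8 alternatives that leave out no single mouse, the biliary score difference between KO and DEN tumours ranged from 1.52 to 2.32. The hepatocyte difference ranged from -3.47 to -1.90, each with a permutation p under 0.05. These include the alternative with each tumour as its own replicate, whose p treats repeat tumours of a mouse as independent. The fit within scan day 1, of 3 and 3 arrays, lay outside both ranges at 2.34 and -3.81, where p cannot fall below 0.100. Leaving out each mouse gave 1.53 to 2.02 (exact permutation p 0.00794 to 0.0159) and -2.94 to -2.26. Under the 4 other scalings shared rises of the tumour models numbered 1294 to 1461 and shared falls 1596 to 1809, and under the 3 planned for it the difference of the chromosome spread was 0.0882 to 0.100.

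With slide as a random block the counts of changed genes fell to 6682 for KO tumour against KO liver, 422 for DEN tumour against WT liver, 11 for KO liver against WT liver and 798 for the difference of the tumour effects. As no slide held more than 1 group, this block sets the group difference against the spread between slides. KO liver against WT liver also moved to 1163 with mouse as a random block, 5449 with array weights, 4541 with only the 2 groups compared, 3225 without the KO tumour mice of slide 5 and 953 without the arrays marked for evaluation; the cause was not tested. Over all alternatives that leave out no single mouse, the counts ranged from 6682 to 16645 (KO tumour against KO liver), 422 to 7355 (DEN tumour against WT liver), 9215 to 14630 (KO against DEN tumours), 11 to 5449 (KO liver against WT liver) and 798 to 9809 (difference of the effects). Leaving out each mouse gave 10704 to 12813, 3637 to 5817, 12502 to 14125, 660 to 2392 and 6012 to 8593 in the same order. KO liver against WT liver fell to 999, 866, 1108 and 1090 without KO liver 1, 2, 3 and 4, and to 660 and 903 without WT liver 3 and 4. Without WT liver 1 and 2 it was 1958 and 2104, so the loss of a mouse is not enough to account for it, and the cause was not tested.

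Over 120 list results and 4377 alternative values, 4145 kept direction and side of the threshold, 195 lost the threshold (60 of them with the estimated correlation), 37 gained it and 0 reversed. For 405 results of named genes and 14440 values the numbers were 13773, 633 (168 with slide as a random block), 28 and 6. The 6 reversals were Dll1 in KO against DEN tumours (-1.13), Xaf1 there (1.90), Tpx2 in KO tumour against KO liver (1.10) and in DEN tumour against WT liver (0.0822), all with the mean of the gene's probes, whose probes read opposite ways, and Fn1 in KO tumour against KO liver with normexp and quantile (0.32) and with the quantile of the processed signal (0.29), where the cause was not tested.

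Signal over background limits the folds of genes that are dim in 1 group, which are given as bounds, and the sizes for dim genes such as Krt7, Epcam and Cdkn1a in liver. The median of all genes in KO against DEN tumours was -0.33 with the main scaling, -0.04 with normexp and quantile, -0.09 with the quantile of the processed signal and -0.27 with the median of probes above background on all arrays.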

Other observations

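The tests of chromosomes were chosen before their results were seen, whereas the single members of the cell lists, the sex-linked genes per array and the chromosomes named here were picked after the result was seen.

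Cell markers within 1 list moved apart in KO tumours, which the list medians hide. Against DEN tumours, the macrophage lysozyme gene Lyz2 (3.099 ± 0.44, adjusted p 2.9e-05) and the pan-macrophage gene Cd68 (1.61 ± 0.32) rose, while Cd5l, a gene of resident Kupffer cells, fell by 3.65 (adjusted p 0.0035, slide-blocked p 0.11). Of 10 endothelial genes, whose list did not pass, 4 fell, among them Clec4g by 4.11 (adjusted p 6.2e-05) and the VEGF receptor gene Kdr by 1.59 (adjusted p 4.6e-05), whereas Pecam1 did not pass (-0.24). Among T cell genes Cd3d rose by 2.27 ± 0.49 and Lck by 1.89 ± 0.42, while Cd3e fell by 1.48 and Cd4 by 3.79. The interferon genes Ifi44 (-2.07 ± 0.34) and Xaf1 (-1.40 ± 0.23) fell and Oasl2 rose (1.14 ± 0.34, slide-blocked p 0.089), but another Xaf1 probe, above background on 20 of 21 arrays, read 5.21. Of glycolysis and hypoxia genes, the carbonic anhydrase gene Car9 rose by 3.15 ± 0.40 and the lactate transporter gene Slc16a3 by 2.79 ± 0.41, while Bnip3 fell by 1.99.

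KO tumours 1 and 2 differed from all other arrays in sex-linked genes, with Eif2s3y at -8.81 and -9.02 and Ddx3y at -8.85 and -9.04, not above background. KO tumours 3 to 6 had Ddx3y at -1.14, -1.87, -0.51 and -0.62, against group means of 0.67 in DEN tumours, 0.70 in KO livers and 0.71 in WT livers. An Xist probe read -1.29 and -1.81 in KO tumours 1 and 2. Sexes are not given in the sources used here, but Xist without Y-linked transcripts is the pattern of female mice. Ddx3y was above background on 7 of 7 DEN tumour, 4 of 4 KO liver and 4 of 4 WT liver arrays. Only the KO tumour group held mice of both patterns, so its comparisons are not matched for them.

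KO tumours may carry larger shifts of whole chromosomes. For each tumour mouse the median log2 difference from the livers of its genotype was taken for each of 19 autosomes (22391 genes). The SD over autosomes was 0.139 ± 0.0231 in KO tumours and 0.0502 ± 0.0120 in DEN tumours (n = 5 each), a difference of 0.0887 (exact two-sided permutation p 0.00794, the smallest possible). Larger changes of single genes wherever they lie are argued against: divided by the SD when genes are dealt to chromosomes at random (100 shuffles), it was 3.15 ± 1.11 and 1.66 ± 0.285, a difference of 1.48 (exact permutation p 0.00794). Relative to the mouse's own median over autosomes, chromosome 15 was at 0.42, 0.46, 0.32, 0.36 and 0.27 in the KO tumour mice and 0.02 to 0.16 in the DEN tumour mice, and chromosome 9 at -0.27, -0.32, -0.07, -0.31 and -0.14 against -0.02 to 0.01. Copy number was not measured, and co-regulated genes that lie together stay open as a source.

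The repeat tumours of a mouse correlated at 0.956 and 0.960 in DEN mice 4 and 5, hybridised on different slides, and at 0.984 in KO tumour mouse 5, on the same slide.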
